A study of Mus musculus with 12 samples.

How the data were processed

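RNA was extracted from brain tissue of male C57BL6 mice with TRIzol and a column kit, per the labels' protocols, and sequenced in 12 libraries, 3 in each of 4 groups. The labels put each library in its group by adolescent treatment (THC or vehicle) and adult treatment (LPS or saline). The brain region, the library kit and the read layout are not given in the sources used here. The submitters' processing notes name STAR 2.5, HTSeq, DESeq2 and the mouse build mm10, without roles or settings. Strandedness, annotation version, read trimming and the handling of reads that map to several places are not given in the sources used here. Reads shared by paralogs, as in the H2-Q, Ifit, Ly6 and Gbp families, or by overlapping and antisense genes could therefore be split or dropped.

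The raw read counts per gene were deposited by the authors, per the file headers, and were the input of every test here. The deposited normalized signal, named so per the file headers, equalled the count divided by a DESeq2 size factor that the authors set separately for the 6 vehicle and the 6 THC libraries, so it was not compared across them. The deposited FPKM equalled the reads divided by gene length and by the total of the file, as checked on the values. An adjusted p-value was deposited by the authors in 1 of the tables, per the file headers. It was compared with a DESeq2 fit of THC_LPS against THC_Ctrl on the 6 THC libraries, and is given only as from the authors' deposited table. Per pretreatment, 24562 genes are listed for vehicle and 24274 for THC, each with at least 1 read over its 6 libraries, so a gene listed in only 1 set was taken as 0 reads in the other. The joined table held 25556 genes, with coordinates as the files give them (mm10). Of the gene IDs, 98.7% were found in GENCODE M21, and 70.1% of those had the same start and end there. Library totals ran from 16.7 to 44.7 M reads, and the transcript Yam1 took 0.643 to 5.46% of them.

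EdgeR 4.0.16 in R 4.3.3 was the main tool. All 12 libraries entered a single fit with a mean per group, TMM scaling, the default expression filter (17208 genes kept), robust quasi-likelihood dispersions and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. The 5 comparisons were LPS after vehicle, LPS after THC, THC without LPS, THC with LPS and their interaction. Levels are printed as CPM (edgeR counts per library size after TMM scaling), and n is 3 per group. The SE of a log2 fold change was derived as its absolute value divided by the square root of edgeR's quasi-likelihood F. It is not an output of the model and is approximate, most of all for genes with few reads or little change. Sets of genes were tested with camera (limma 3.58.1, statmod 1.5.0) on voom values with an estimated correlation between genes, 2-sided, adjusted over 36 lists of inflammatory, cell type, brain region and stress genes. Of 660 list entries, 658 matched the files, 4 of them through newer names, such as Ccn1 for Cyr61. Lists with fewer than 5 tested members were not tested. The design, tests, lists, named-gene rule and alternatives were fixed before the data were examined, except where a choice is said to come later.

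The named-gene rule took, per comparison, the 8 largest rises and the 8 largest falls among called genes with a mean of at least 1 CPM whose groups did not overlap. Where fewer than 4 qualified it took the 5 smallest p. It added up to 4 members with the smallest p of each described list, and P2ry12, Tmem119, Cx3cr1, Aif1, Il1b, Tnf, Il6, Ccl2, Lcn2, Cnr1 and Cnr2 in every comparison. Gh, Prl and Pomc, and the summed Hox genes, fall outside the rule and were named after their values were seen. Which gene and list results were carried through the alternatives was settled after the files were seen and after reversals over a wider set had been counted.

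The alternatives were DESeq2 1.42.0, voom with sample weights, median-ratio size factors, no expression filter, a filter of 1 CPM in 3 libraries, an added log2 fold change of 1, a fit of only the compared groups, the replicate number as a block, a preset correlation of 0.01, and each library left out in turn with filter and scaling recomputed. Removal of each library's loess trend on GC content (span 0.5), and leaving out Veh_LPS replicate 2 and THC_LPS replicate 3 together, were added after seeing the data. A GC value was at hand for 99.3% of tested genes. No 2 libraries of a group were close enough to be a single library deposited again (smallest chi-square per degree of freedom 11.2). The procedure was tested on simulated counts for LPS after vehicle over 16923 genes, where edgeR recovered 26.6% of genes changed 1.5-fold, 75.8% at 2-fold and 90.5% at 4-fold, and 2.99% of 134 calls were false. A straight-line GC trend of a set slope, not the trend fitted to the data, was then put on the simulated THC_LPS replicate 3. With it, edgeR recovered 13.8%, 71.6% and 85.7% over 16935 genes, and 1.71% of 117 calls were false. After trend removal it recovered 16.9%, 74.6% and 85.7%, and 4.62% of 130 calls were false. That library is not in the simulated comparison, so its trend acted only through the shared fit. Simulated genes varied independently of each other, without length or tissue trends. The recovered and false shares therefore need not hold for the real libraries. A count of 0 reads in a group gives no fold change in the text, and 3 libraries against 3 cannot give an exact permutation p under 0.1, so single genes were tested only in the model across genes. Symbols that are only clone numbers were counted but not named.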

Results

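Gene expression was measured by RNA sequencing in brain tissue of male C57BL6 mice. The animals received delta-9-tetrahydrocannabinol (THC), the main psychoactive compound of cannabis, at 5 mg/kg or its vehicle from postnatal day 30 to 44. As adults, at day 70, they received lipopolysaccharide (LPS), a bacterial cell wall component that triggers innate immunity, at 0.33 mg/kg or saline, and brains were taken 24 h later. The 12 libraries formed 4 groups of 3, named here Veh_Ctrl, THC_Ctrl, Veh_LPS and THC_LPS. Gene counts summed to 24.3 to 26.4 M reads per library in Veh_Ctrl, 24.7 to 25.6 M in THC_Ctrl, 25.5 to 44.7 M in Veh_LPS and 16.7 to 22.4 M in THC_LPS. Of 25556 genes, 17208 had enough reads to be tested. The labels do not state that the 3 libraries of a group came from separate mice, so p-values measure the spread between these samples, which may be partly technical.

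Libraries differed in the following ways. THC_LPS replicate 3 had a Spearman correlation of -0.842 between its gene levels, relative to the median library, and GC content, against -0.149 to 0.357 in the other 11 libraries. Mitochondrial transcripts made up 9.11% of its reads, against 4.11 to 7.11% elsewhere. Spearman correlations of gene levels with gene length ran from -0.506 in Veh_LPS replicate 1 to 0.481 in THC_LPS replicate 2. In replicates 1, 2 and 3 they were 0.17, 0.481 and 0.245 for THC_LPS and 0.233, -0.409 and -0.327 for THC_Ctrl. For Veh_LPS they were -0.506, 0.275 and 0.219, and for Veh_Ctrl -0.0378, -0.38 and 0.0425. No alternative analysis removed these length trends. Veh_LPS replicate 2 held pituitary hormone transcripts: Gh reached 3638 CPM (read count scaled to library size) there and at most 10.6 CPM in any other library, Prl 222 against at most 0.706 CPM elsewhere, and Pomc 274 against at most 3.45 CPM. Homeobox genes of the Hox clusters, which mark caudal parts of the nervous system, summed to 17 to 21.5 CPM in Veh_LPS, 0 to 2.08 in Veh_Ctrl, 1.54 to 15.2 in THC_Ctrl and 0.342 to 14.2 in THC_LPS.

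The first comparison asked how the adult brain responded to LPS after vehicle in adolescence. Antiviral, complement, antigen presentation and acute inflammation genes rose. Irf7, a transcription factor of the interferon response (ENSMUSG00000025498, chromosome 7, 141262706 to 141266481, mm10), went from 2.11 ± 0.47 CPM in Veh_Ctrl to 18.7 ± 1.1 in Veh_LPS (SD, n = 3 each), a log2 fold change of 3.15 ± 0.27 (SE; edgeR adjusted p = 4.75e-05). Lcn2, which encodes the acute-phase protein lipocalin 2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32387797), went from 0.165 ± 0.13 to 19.9 ± 10 CPM, a log2 fold change of 6.89 ± 0.68 (edgeR adjusted p = 0.000225). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 107 genes rose and 0 fell, with 1282 genes at an unadjusted p under 0.05 where 860 would be expected by chance. DESeq2 called 202 genes, 197 higher and 5 lower, and limma-voom with sample weights called 891 higher and 1004 lower. All 3 LPS libraries lay beyond all 3 control libraries for 16% of genes, where chance gives 10%.

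Interferon-stimulated genes formed the largest called group, with 20 of 28 measured members higher and 26 higher when adjusted over the list alone (median log2 fold change 1.81; camera adjusted p = 0.00634). Among them, Rsad2, which blocks viral replication, had a log2 fold change of 2.39 ± 0.26, Oasl2 of 2.07 ± 0.26 and Ifitm3 of 1.94 ± 0.24. Zbp1, a sensor of viral nucleic acid, went from 0.217 ± 0.016 to 2.49 ± 1.5 CPM. Ifi204, a gene outside the list, rose by 3.09 ± 0.61 on the log2 scale. Antigen presentation genes rose in 9 of 20 cases and in 14 adjusted over the list alone (median 0.90; camera adjusted p = 0.0133). H2-K1, a classical class I molecule, rose by 1.39 ± 0.21 on the log2 scale and B2m, its light chain, by 0.90 ± 0.14. H2-Q4 rose by 1.77 ± 0.23 and H2-Q7 by 2.49 ± 0.33, values that are uncertain because these loci share near-identical sequence and the counting could have split their reads.

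Complement and phagocytosis genes rose in 8 of 19 cases, 12 adjusted over the list alone (camera adjusted p = 0.00491). C4b, a classical pathway component, went from 25.3 ± 3.8 to 71.6 ± 11 CPM, C3 had a log2 fold change of 2.85 ± 0.56, and the scavenger receptor gene Msr1 stood at 0.0138 CPM (1 read) in Veh_Ctrl and 1.01 ± 0.74 CPM in Veh_LPS. Of 28 acute inflammation genes, 5 rose, 17 adjusted over the list alone (camera adjusted p = 0.0115), including Saa3, an acute-phase protein gene, by 5.61 ± 0.78 on the log2 scale. Reactive astrocyte genes rose in 3 of 20 cases, namely Serpina3n, Lcn2 and Cxcl10, and in 12 adjusted over the list alone (camera adjusted p = 0.00491). Lcn2 and Cxcl10 are also in other lists. Serpina3n, a protease inhibitor gene of reactive astrocytes, rose by 1.08 ± 0.22, while Gfap had 0.68 ± 0.16 (edgeR adjusted p = 0.0911) and was called in 8 of 21 alternative analyses, among them DESeq2 (adjusted p = 0.00595), voom with sample weights (0.000787) and edgeR with GC trends removed (0.00308) or without THC_LPS replicate 1 or 3 (0.0259 and 0.00227). The chemokine gene Cxcl10 rose by 3.08 ± 0.61 as the 1 called gene of 12 cytokines and chemokines, with 6 higher adjusted over the list alone (camera adjusted p = 0.0115). Il1b had a log2 fold change of 1.58 ± 0.79 (edgeR adjusted p = 0.697). Tnf, Il6 and Ccl2 were too low to test, with 0, 0 and 0 reads in Veh_Ctrl and 14, 1 and 62 in Veh_LPS.

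Myeloid genes shared by microglia and macrophages rose in 8 of 20 cases, 16 adjusted over the list alone (median 0.84; camera adjusted p = 0.00634), with Fcer1g higher by 1.19 ± 0.17, C1qb by 0.96 ± 0.15, Fcgr3 by 1.13 ± 0.19 and Itgam by 0.91 ± 0.15 on the log2 scale. Activated microglia genes passed as a list (1 of 18 called, Lyz2 at 1.19 ± 0.17; 6 adjusted over the list alone; camera adjusted p = 0.0115). Homeostatic microglia genes did not pass, with a camera adjusted p = 0.0799, and 1 of 20 rose, Olfml3 by 0.87 ± 0.15, with 5 adjusted over the list alone. P2ry12, a purinergic receptor gene of resting microglia, had a log2 fold change of -0.50 ± 0.23 (edgeR adjusted p = 0.656), Tmem119 0.36 ± 0.17, Cx3cr1 0.24 ± 0.13 and Aif1 0.79 ± 0.31, none past the threshold in edgeR, although voom with sample weights called P2ry12 lower (adjusted p = 0.0039) and Aif1 higher (0.0273). Blood leukocyte markers rose in 3 of 9 cases, 4 adjusted over the list alone (camera adjusted p = 0.00634), with Plac8 at 3.47 ± 0.62 and Ly6c2 at 3.67 ± 0.73. Endothelial activation genes rose in 4 of 15 cases, 7 adjusted over the list alone (camera adjusted p = 0.0169), including the adhesion molecules Icam1 at 1.88 ± 0.39 and Sele at 3.65 ± 0.74. Endothelial markers rose in 3 of 20 cases, 5 adjusted over the list alone (camera adjusted p = 0.0234), namely Vwf, Ly6a and Ly6c1. Of 25 toll-like receptor and NF-kB genes Icam1 alone was called, with 2 adjusted over the list alone (camera adjusted p = 0.0133).

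The endocannabinoid genes held 0 calls of 19 in edgeR, also adjusted over the list alone, with 17 of 19 negative (median -0.17; camera adjusted p = 0.095). Cnr1, which encodes the cannabinoid receptor CB1, had a log2 fold change of -0.26 ± 0.18, and Cnr2, which encodes CB2, -0.92 ± 0.78. Astrocyte, oligodendrocyte, oligodendrocyte precursor, neuronal, pericyte, choroid plexus, meningeal, erythrocyte, pituitary and regional neuron lists held 0 genes called by edgeR, and 0 adjusted over each list alone. The 7 measured pituitary genes were all positive (median 2.40, or -0.02 without Veh_LPS replicate 2; camera adjusted p = 0.372). Border-associated macrophage markers held 1 called gene of 12, Siglec1, and 3 adjusted over the list alone (camera adjusted p = 0.0855). Hoxb8, with 0 reads in Veh_Ctrl and 3.15 ± 0.81 CPM in Veh_LPS, and Hoxa5, with 0.0277 ± 0.048 and 3.86 ± 0.37 CPM, were also called. They missed the threshold with GC trends removed (edgeR adjusted p = 0.121 and 0.109) and with no low-count filter (0.525 and 0.314).

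All 12 lists that passed were higher, and did so with a preset correlation of 0.01 as well as with the estimated correlation used here. With the preset value 27 passed, 21 higher and 6 lower. With the estimated correlation 1 list passed as lower without Veh_Ctrl replicate 3, and 1 without Veh_LPS replicate 1. Several of the 12 share members, such as Lcn2, Cxcl10, Icam1, Vwf, Itgam and Lyz2, so they are not 12 separate responses. The count of called genes rested on single libraries, being 33 without Veh_Ctrl replicate 1, 39 without Veh_Ctrl replicate 2, 49 without Veh_LPS replicate 2, 43 without Veh_LPS replicate 3 and 197 without THC_LPS replicate 3. Irf7, Lcn2, Rsad2, Oasl2, Ifitm3, H2-Q4, H2-Q7, Saa3, Lyz2, C4b, Fcer1g, B2m and C1qb stayed called in each of 21 alternative analyses. Vwf, H2-K1, Ly6a, Msr1 and Zbp1 missed the threshold in edgeR without Veh_Ctrl replicate 1, at adjusted p of 0.052, 0.052, 0.0537, 0.0722 and 0.052, and Zbp1 also without Veh_Ctrl replicate 2, at 0.0531. Fcgr3 missed it without Veh_Ctrl replicate 2 (edgeR adjusted p = 0.0589) and Veh_LPS replicate 2 (0.0528). Itgam, Ly6c1, Olfml3, Plac8, Ifi204, C3, Cxcl10, Ly6c2, Serpina3n, Icam1, Sele, Hoxa5 and Hoxb8 missed it without Veh_Ctrl replicate 1, with edgeR adjusted p from 0.0852 for Itgam to 0.255 for Icam1 and Sele, and without Veh_Ctrl replicate 2, from 0.0578 for Itgam to 0.26 for Sele. Some of these also missed it without Veh_Ctrl replicate 3 (edgeR adjusted p up to 0.136, Cxcl10), Veh_LPS replicate 2 (up to 0.214, Serpina3n) or Veh_LPS replicate 3 (up to 0.283, Icam1). Hoxb8 missed it without any of 10 libraries, among them Veh_LPS replicate 1 (edgeR adjusted p = 0.0565), THC_Ctrl replicate 1 (0.0907) and THC_LPS replicates 1, 2 and 3 (0.083, 0.11 and 0.0577). Hoxa5 missed it without THC_Ctrl replicate 1 (0.0524) and THC_LPS replicate 2 (0.0693), Icam1 without THC_Ctrl replicate 1 (0.0562) and THC_LPS replicate 3 (0.0518), and Sele without THC_LPS replicates 1 and 2 (0.0504 and 0.0654), all by edgeR adjusted p. C3 missed it with no low-count filter (edgeR adjusted p = 0.184), and C3, Ly6c2, Icam1, Sele and Hoxb8 with Veh_LPS replicate 2 and THC_LPS replicate 3 both left out (0.0581, 0.0601, 0.158, 0.0874 and 0.158). Without THC_LPS replicate 3 the number of passing lists was 7, and the activated microglia, toll-like receptor, acute inflammation, endothelial and endothelial activation lists missed the threshold at camera adjusted p of 0.0617 to 0.073. The last 4 of these also missed it without Veh_Ctrl replicate 3, at 0.0517 to 0.0682. The homeostatic microglia list passed without THC_Ctrl replicate 3 (camera adjusted p = 0.023) and without Veh_LPS replicate 2 (0.0373).

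The next comparison asked how the brain responded to LPS after THC in adolescence. Interferon, myeloid and endothelial genes were again among those that rose, and Cyr61 and Ddit4 were lower in THC_LPS than in THC_Ctrl. Of the 4 groups, THC_Ctrl had the highest mean of Cyr61. Lcn2 went from 0.105 ± 0.097 CPM in THC_Ctrl to 11.1 ± 6.4 in THC_LPS (SD, n = 3 each), a log2 fold change of 6.64 ± 0.74 (edgeR adjusted p = 0.00213). Irf7 went from 2.67 ± 0.35 to 11.3 ± 4.9 CPM, a log2 fold change of 2.08 ± 0.26 (edgeR adjusted p = 0.0051). Ptprc, the common leukocyte antigen gene, rose by 1.91 ± 0.30, Siglec1, a sialic acid receptor of macrophages, by 2.22 ± 0.33 and Cybb, a subunit of the phagocyte oxidase, by 1.75 ± 0.31 on the log2 scale. Cyr61, an immediate early gene for a matrix protein (ENSMUSG00000028195, chromosome 3, 145646971 to 145649985), went from 19.9 ± 3.3 to 5.24 ± 0.26 CPM, a log2 fold change of -1.92 ± 0.31 (edgeR adjusted p = 0.0248). Ddit4, a stress-responsive inhibitor of mTOR signalling, went from 51.3 ± 8.4 to 27.5 ± 2.2 CPM. EdgeR's test called 19 genes, 17 higher and 2 lower, with 3337 at an unadjusted p under 0.05, and DESeq2 called 334 higher and 119 lower. Voom with sample weights called 543 higher and 432 lower. The groups did not overlap for 23.3% of genes, where chance gives 10%. Gene-length trends differed between most of these libraries and were not removed, and their part in this excess was not tested.

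Of 28 interferon-stimulated genes 2 rose, Irf7 and Ifit1 (2.47 ± 0.44, in a family with shared sequence), and 23 rose when adjusted over the list alone. The list's median was 1.08, with a camera adjusted p = 0.122 with an estimated correlation. With GC trends removed, edgeR called 12 of the 28 after THC and 24 after vehicle, 6 and 10 of 20 myeloid genes, 3 and 10 of 19 complement and phagocytosis genes, and 1 and 11 of 20 antigen presentation genes. The counts were 4 and 2 of 20 for homeostatic microglia genes, and equal at 3 and 3 for endothelial and for blood leukocyte markers. Gbp7 and Samd9l, 2 interferon-induced genes outside the list, rose by 1.71 ± 0.23 and 1.64 ± 0.29. Of 20 myeloid genes 2 rose, Ptprc and Ly86 (1.48 ± 0.25), and 10 adjusted over the list alone, with a camera adjusted p = 0.129. Fcer1g had a log2 fold change of 0.80 ± 0.17 and C1qb 0.70 ± 0.15, with edgeR adjusted p of 0.0775 and 0.0736, and both were called by DESeq2 (0.00392 and 0.00269). Homeostatic microglia genes held 0 calls of 20 in edgeR and 5 higher adjusted over the list alone (camera adjusted p = 0.193), with P2ry12 at 0.01 ± 0.23, Tmem119 at -0.07 ± 0.17 and Cx3cr1 at 0.51 ± 0.13. DESeq2 called Cx3cr1 (adjusted p = 0.0182), as did edgeR with GC trends removed (0.046). Activated microglia genes held 1 call of 18, Lyz2 at 1.23 ± 0.18, also adjusted over the list alone (camera adjusted p = 0.207). Blood leukocyte markers rose in 2 of 9 cases, Lyz2 and Plac8 (3.84 ± 0.62), 4 adjusted over the list alone (camera adjusted p = 0.112). Of 15 endothelial activation genes Lcn2 and Sele rose, the latter from 0 reads in THC_Ctrl to 0.657 ± 0.24 CPM, with 9 higher adjusted over the list alone (camera adjusted p = 0.122).

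Complement and phagocytosis genes held 0 calls of 19 in edgeR and 7 higher adjusted over the list alone (camera adjusted p = 0.112). Lcn2 was the 1 called gene of 20 reactive astrocyte genes, with 9 higher adjusted over the list alone (camera adjusted p = 0.112), and of 28 acute inflammation genes, with 9 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.399). Antigen presentation genes held 0 calls of 20 in edgeR and 1 higher adjusted over the list alone (median 0.11; camera adjusted p = 0.765). Their mean log2 level relative to Veh_Ctrl was 0.71, 0.28 and -0.13 in THC_LPS replicates 1, 2 and 3, against 0.11 to 0.27 in THC_Ctrl, and the median log2 fold change was -0.20 without THC_LPS replicate 1, 0.29 without THC_LPS replicate 3 and 0.19 with GC trends removed. It also moved by over 1.5 times, with its sign kept, without THC_Ctrl replicate 1 or 3. Cytokines and chemokines held 0 calls of 12 in edgeR and 3 higher adjusted over the list alone (camera adjusted p = 0.122), with Cxcl10 at 3.52 ± 0.72 (edgeR adjusted p = 0.0736) and Il1b at 1.45 ± 0.88. Immediate early genes fell in 1 of 20 cases, Cyr61, and in 15 adjusted over the list alone (median -1.08; camera adjusted p = 0.129). Their mean log2 level relative to Veh_Ctrl was 1.1 in THC_Ctrl, 0.17 in Veh_LPS and 0.15 in THC_LPS. The same THC_Ctrl libraries thus enter this fall, the higher values for THC without LPS and the negative interaction. Endocannabinoid genes held 0 calls of 19 in edgeR and 1 lower adjusted over the list alone (camera adjusted p = 0.824), with Cnr1 at 0.19 ± 0.18 and Fabp5 at -0.60 ± 0.16. Among lists of other cell types, endothelial markers held 1 call of 20 by edgeR, Ly6a (6 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.122), and border-associated macrophage markers 1 of 12, Siglec1. Astrocyte, oligodendrocyte, precursor, neuronal, pericyte, choroid plexus, meningeal, erythrocyte, pituitary and regional neuron lists held 0 genes called by edgeR. With GC trends removed edgeR called 1 precursor and 1 neuronal gene, both higher, and 0 in the others. In the authors' deposited table the adjusted p, matched by DESeq2, was 0.00066 for Hba-a1 and Hbb-bt, 0.0117 for Opalin and 0.0489 for Celf4. Adjusted over each list alone, 4 neuronal markers were higher and 2 lower, 3 myelin genes higher and 3 lower, 2 pericyte markers higher, 1 thalamic and hypothalamic marker lower, and 10 of 20 nuclear-encoded oxidative phosphorylation genes lower (camera adjusted p = 0.324).

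No list passed camera with an estimated correlation, and 15 did with the preset value of 0.01, 10 higher and 5 lower. The count of 19 depended on single libraries, being 0 without THC_Ctrl replicate 1, 2 without THC_Ctrl replicate 2, 1 without THC_Ctrl replicate 3, 11 without Veh_Ctrl replicate 3, 8 and 7 without Veh_LPS replicate 2 and 3, 57 without Veh_LPS replicate 1, 160 without THC_LPS replicate 1 and 29 without THC_LPS replicate 2. Without THC_Ctrl replicate 1 the smallest edgeR adjusted p was 0.052, shared by Lcn2, Irf7 and Gbp7, with 3236 genes at an unadjusted p under 0.05. Irf7, Gbp7, Lyz2 and Ptprc reached 0.0572 by edgeR without THC_Ctrl replicate 3, and Gbp7, Lyz2, Siglec1 and Ptprc 0.0837 to 0.183 without THC_Ctrl replicate 2. Cyr61 missed the threshold without any THC_Ctrl library (edgeR adjusted p = 0.0657, 0.173 and 0.112), without Veh_Ctrl replicate 3 (0.0558) and without THC_LPS replicate 2 or 3 (0.0812 and 0.115). Plac8, Ly86, Ddit4, Ifit1, Samd9l and Cybb missed it without any THC_Ctrl library, without Veh_LPS replicate 2 or 3, and, except Plac8, without Veh_Ctrl replicate 3, with edgeR adjusted p up to 0.266 (Ifit1 and Samd9l without THC_Ctrl replicate 2). Cybb also missed it without Veh_Ctrl replicate 1 or 2 (edgeR adjusted p = 0.0587 and 0.0657), Ddit4 without THC_LPS replicate 2 (0.0845), and all of these but Ly86 without THC_LPS replicate 3 (0.0559 to 0.0969). When the fit held only the 6 THC libraries, Lcn2 and Cyr61 stayed called. Ddit4 had -0.62 with GC trends removed (edgeR adjusted p = 0.0671) against -0.90 before. With the strict low-count filter Ddit4, Ifit1 and Samd9l missed the threshold (edgeR adjusted p = 0.0661, 0.0619 and 0.0619), as did Lcn2 with voom and sample weights (0.0635). With Veh_LPS replicate 2 and THC_LPS replicate 3 both left out, Cyr61, Plac8, Ifit1, Samd9l and Cybb missed it (edgeR adjusted p = 0.136, 0.0848, 0.0816, 0.0777 and 0.126). Some genes passed without a single library: C1qb (0.0248) and Cxcl10 (0.0437) without THC_LPS replicate 3, Fcer1g (0.0159) without THC_LPS replicate 2 and Ccl12 (0.0307) without Veh_LPS replicate 1, by edgeR adjusted p.

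The authors' deposited table gave an adjusted p for 16921 genes, and these ranked as in a DESeq2 fit of THC_LPS against THC_Ctrl on the 6 THC libraries (Spearman correlation 1). An adjusted p under 0.05 was given to 145 genes in the authors' deposited table, among them all 19 called here by edgeR, and 34 of them were also called by edgeR for LPS after vehicle. The DESeq2 refit itself called 152 genes, with 145 called by both. By that refit, 119 of the 145 were higher with LPS and 26 lower. In the authors' deposited table the adjusted p, matched by DESeq2, was 3.91e-14 for Cyr61, 5.37e-07 for Irf7, 0.0012 for Ddit4, 0.00311 for Lcn2 and 0.00281 for Fosb, an activity-regulated transcription factor gene.

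**Figure D1:**
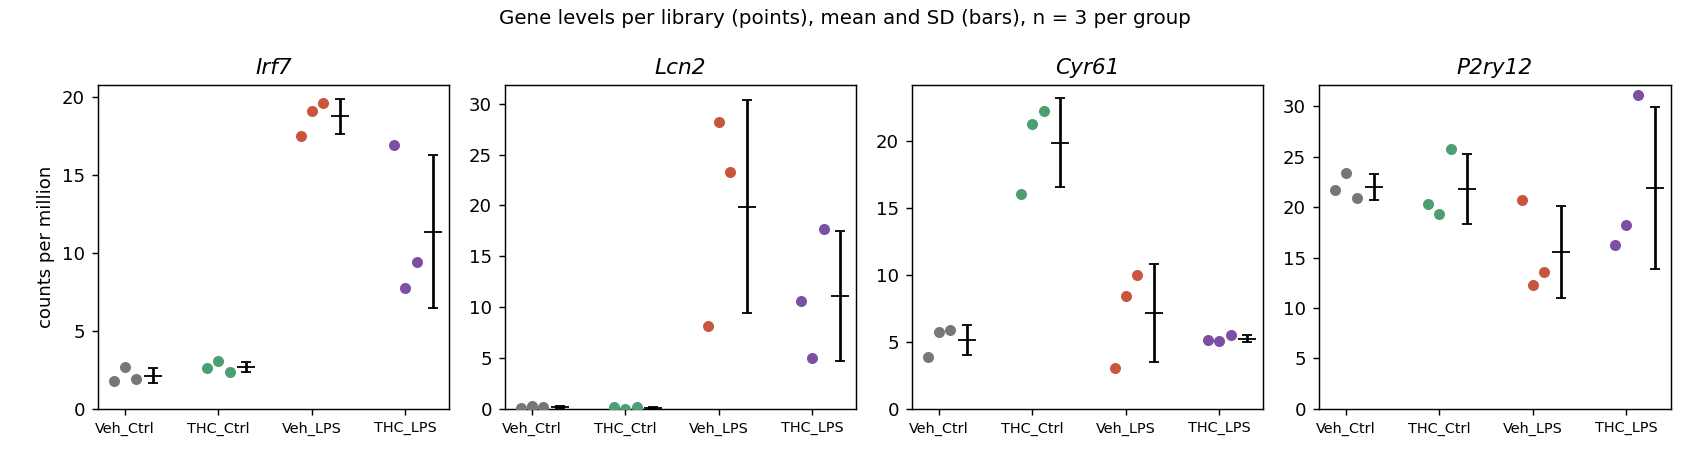
Normalised read counts (CPM) of Irf7, Lcn2, Cyr61 and P2ry12 in each library of the 4 groups, with points for libraries and the mean and SD (n = 3). Irf7 means were 2.11, 2.67, 18.7 and 11.3 CPM in Veh_Ctrl, THC_Ctrl, Veh_LPS and THC_LPS, and Cyr61 means were 5.15, 19.9, 7.17 and 5.24 CPM.

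The 2 LPS responses were compared directly. Of the genes called, 15 rose in both, including Irf7, Lcn2, Lyz2, Plac8, Siglec1, Ifit1, Gbp7, Cybb and Ly86, where 0.106 would be expected by chance (2-sided Fisher's exact test over genes, p = 3.89e-32). That test treats genes as independent, which they are not, and both comparisons share a dispersion per gene. Its p therefore does not measure the spread between samples. Of the 107 genes called after vehicle, 102 (95.3%) also had a positive log2 fold change after THC, with medians of 1.60 and 0.87. The genes were chosen on the vehicle libraries, so the smaller median after THC is partly a result of that choice. Across all 17208 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.323 and a Spearman correlation of 0.237. At an unadjusted p under 0.01 in both, 125 genes were higher and 7 lower in both comparisons.

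**Figure D2:**
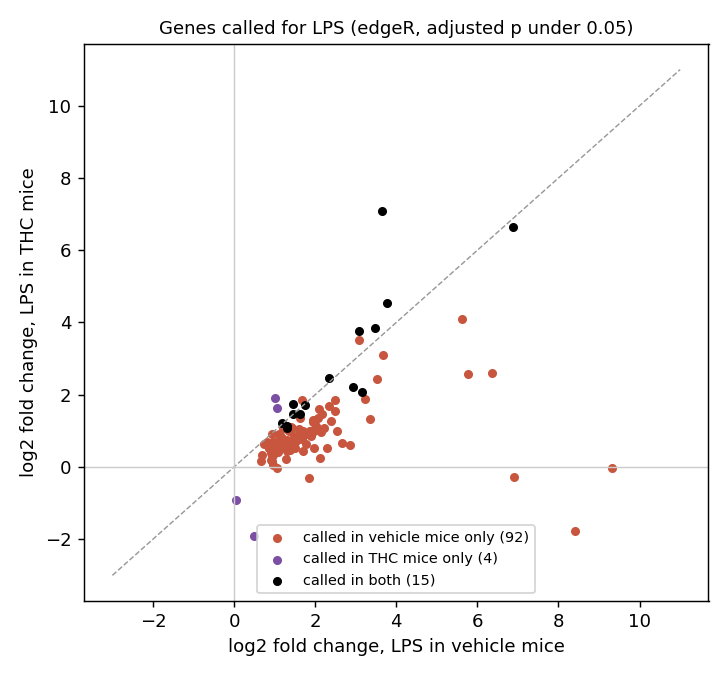
Log2 fold change with LPS after vehicle (x axis) against that after THC (y axis), for genes called by edgeR in either comparison. Colours mark 92 genes called after vehicle only, 4 after THC only and 15 after both. Tested genes called in neither are not drawn. Most called genes lie above 0 on both axes.

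The interaction asked whether the response to LPS differed after THC. EdgeR called 0 genes (smallest adjusted p = 0.71), with 1167 at an unadjusted p under 0.05. DESeq2 called 1 gene, Cyr61 (adjusted p = 0.00165), and voom with sample weights 0. Cyr61 had the smallest p, with an interaction of -2.42 ± 0.44 on the log2 scale, followed by values of -2.14 ± 0.46 for Psmb8, an immunoproteasome subunit gene, -1.06 ± 0.23 for Egr1 and -1.61 ± 0.36 for Fosb, none past the threshold in edgeR. Hoxb6 stood at 0, 0.749, 1.67 and 0.21 CPM in Veh_Ctrl, THC_Ctrl, Veh_LPS and THC_LPS. Without Veh_LPS replicate 1 edgeR called Cyr61 (adjusted p = 0.0015) as its 1 gene, and camera passed 2 lists. With all 12 libraries, edgeR's test of the difference thus passed for no gene called in 1 of the LPS responses and not in the other, while DESeq2's passed for Cyr61.

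Antigen presentation genes had negative interaction values in 20 of 20 cases (median -0.78), 11 lower adjusted over the list alone, with a camera adjusted p = 0.343 with an estimated correlation. Immediate early genes were negative in 20 of 20 cases (median -1.32), 13 lower adjusted over the list alone (camera adjusted p = 0.343). Their mean log2 level was highest in THC_Ctrl (1.1 relative to Veh_Ctrl, against 0.17 in Veh_LPS and 0.15 in THC_LPS). Interferon-stimulated genes were negative in 23 of 28 cases (median -0.66, or -0.43 without THC_LPS replicate 2), 0 adjusted over the list alone in edgeR (camera adjusted p = 0.415). The camera adjusted p was 0.959 for homeostatic microglia, 0.415 for myeloid, 0.496 for activated microglia, 0.973 for cytokine and 0.415 for endocannabinoid genes, each with 0 calls by edgeR and 0 adjusted over the list alone. P2ry12 had an interaction of 0.51 ± 0.32, Tmem119 -0.42 ± 0.24, Cx3cr1 0.27 ± 0.19, Cnr1 0.45 ± 0.25 and Lcn2 -0.25 ± 1.6. With GC trends removed P2ry12, Tmem119 and Cnr1 stood at 0.15, -0.15 and 0.26, and without THC_LPS replicate 3 at 0.17, -0.25 and 0.22. Lists of other cell types held 0 genes called by edgeR, and adjusted over each list alone 1 pericyte marker was higher. All 7 pituitary genes had negative values (camera adjusted p = 0.814), Veh_LPS replicate 2 being the library with the hormone transcripts. With a preset correlation 13 lists passed, 2 higher and 11 lower, and 0 with the estimated one.

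**Figure D3:**
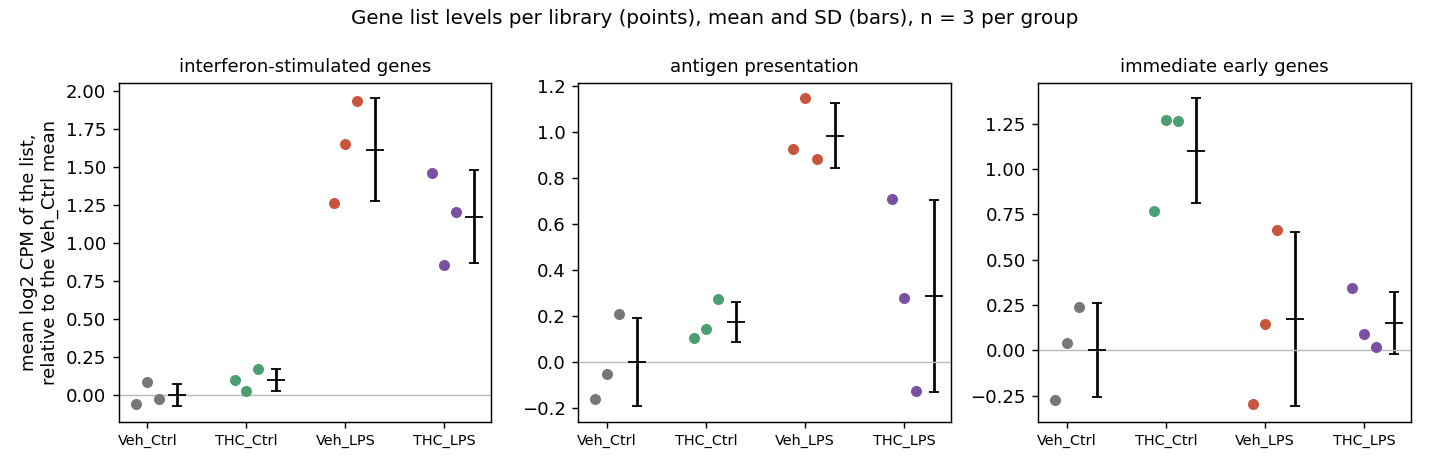
Mean log2 CPM of the interferon-stimulated, antigen presentation and immediate early genes in each library, relative to the Veh_Ctrl mean, with group mean and SD (n = 3). Interferon-stimulated genes averaged 1.61 ± 0.34 in Veh_LPS and 1.17 ± 0.3 in THC_LPS, and immediate early genes 1.1 ± 0.29 in THC_Ctrl.

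The next comparison asked what adolescent THC left in the adult brain without LPS. The genes with the smallest p were immediate early genes, some of which neurons switch on after activity. All had higher values in THC_Ctrl than in Veh_Ctrl and none passed the threshold in edgeR. RNA came from brain tissue, so which cells held these transcripts was not measured. Cyr61 went from 5.15 ± 1.1 to 19.9 ± 3.3 CPM (SD, n = 3 each), a log2 fold change of 1.95 ± 0.31 (edgeR adjusted p = 0.0939). Egr1, a zinc finger transcription factor, went from 149 ± 25 to 305 ± 54 CPM and Fosb from 9.98 ± 2.4 to 29.2 ± 7.9 CPM, with the same adjusted p. Nr4a1, an orphan nuclear receptor, went from 60.8 ± 15 to 195 ± 51 CPM (edgeR adjusted p = 0.127), and Dusp1, a phosphatase of MAP kinases, from 37.5 ± 8.6 to 91 ± 18 CPM (edgeR adjusted p = 0.161). EdgeR called 0 genes, with 623 at an unadjusted p under 0.05 against 860 expected by chance. DESeq2 called 14 (13 higher and 1 lower), with adjusted p of 6.82e-06 for Cyr61, 7.22e-06 for Egr1, 1.78e-05 for Fosb, 0.000234 for Dusp1 and 0.0162 for Nr4a1, and voom with sample weights called 36 higher and 61 lower. Groups did not overlap for 12.8% of genes, against 10% by chance.

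Immediate early genes were positive in 20 of 20 cases (median 1.08), 15 higher adjusted over the list alone, with a camera adjusted p = 0.0631 with an estimated correlation and 1.24e-40 with the preset one. The list passed without Veh_Ctrl replicate 3 (camera adjusted p = 0.0493), THC_Ctrl replicate 1 (0.0375) and Veh_LPS replicate 3 (0.0295). It also passed with the replicate number as a block, where edgeR called 7 genes. A fit of only the compared groups called 9. EdgeR called 5 genes without Veh_LPS replicate 3, among them Cyr61, Egr1, Fosb and Nr4a1 (adjusted p = 0.0285), 3 without THC_Ctrl replicate 1, among them Egr1 and Fosb (0.0463), and 1 without Veh_LPS replicate 1, Cyr61 (0.000941). Endocannabinoid genes were negative in 17 of 19 cases (median -0.12; camera adjusted p = 0.217), with 0 calls in edgeR and 0 adjusted over the list alone, and the list passed without Veh_Ctrl replicate 3 (0.0493). Its median ran from -0.19 without Veh_Ctrl replicate 3 to -0.07 without THC_Ctrl replicate 1. Mgll, which encodes a lipase that breaks down 2-arachidonoylglycerol, had a log2 fold change of -0.36 ± 0.13, Cnr1 -0.18 ± 0.18 and Cnr2 -1.76 ± 0.87, each with an edgeR adjusted p = 1. Voom with sample weights called Mgll (adjusted p = 0.0432), and Cnr2 ran from -3.40 to -1.26 over 18 alternatives.

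Microglia and cytokine genes held 0 calls in edgeR and 0 adjusted over each list alone, with a camera adjusted p of 0.781 for homeostatic, 0.992 for myeloid, 0.788 for activated microglia and 0.781 for cytokine genes. P2ry12 had a log2 fold change of -0.01 ± 0.23, Tmem119 -0.04 ± 0.17, Aif1 -0.14 ± 0.32, Lcn2 -0.59 ± 1.3 and Il1b -0.28 ± 0.95, and Tnf and Il6 had 0 reads in both groups. Lyz2 had -0.52 ± 0.18, Gpr84 -1.02 ± 0.48 and Laptm5 0.28 ± 0.13, each with an edgeR adjusted p = 1. Lists of other cell types held 0 genes called by edgeR, and 1 oligodendrocyte precursor marker was lower adjusted over the list alone. Cerebellar neuron markers were positive in 13 of 14 cases (median 0.28; camera adjusted p = 0.104), cortical and hippocampal ones negative in 15 of 16 (median -0.20; 0.397), striatal ones negative in 15 of 16 (median -0.20; 0.397) and choroid plexus ones positive in 16 of 17 (median 0.42; 0.397). General neuronal markers had a mean log2 level of -0.1 ± 0.08 relative to Veh_Ctrl. With GC trends removed they were positive in 2 of 20 cases (median -0.06; camera adjusted p = 0.412). Without Veh_Ctrl replicate 1 the cerebellar, cortical and choroid plexus medians were 0.19, -0.11 and 0.22. Mitochondrially encoded genes were positive in 12 of 12 cases (median 0.23; camera adjusted p = 0.551) and glucocorticoid-responsive genes in 12 of 18 (median 0.14; 0.551), the latter with a median of 0.00 without THC_Ctrl replicate 3.

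The last comparison asked how the brains of LPS-treated mice differed by adolescent treatment. EdgeR called 0 genes (smallest adjusted p = 0.468), with 1771 at an unadjusted p under 0.05, and DESeq2 and voom with sample weights each called 1 higher and 1 lower. These were Dlx6os1, a long noncoding RNA of the Dlx locus, at 11.5 ± 0.52 CPM in Veh_LPS and 22 ± 5 in THC_LPS (SD, n = 3 each), and H2-Q6, a non-classical class I gene, at 8.16 ± 0.4 and 1.99 ± 1.1 CPM. The DESeq2 adjusted p was 0.00142 for Dlx6os1 and 0.00338 for H2-Q6, against 0.468 and 0.478 in edgeR. H2-Q6 shares sequence with its neighbours, so its value is uncertain. The next smallest p belonged to Clca1 (1.52 ± 0.33), Psmb8 (-1.43 ± 0.32) and Otop2 (1.36 ± 0.30), none past the threshold. Groups did not overlap for 11.7% of genes, against 10% by chance.

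Antigen presentation genes were negative in 19 of 20 cases (median -0.66), 12 lower adjusted over the list alone, with a camera adjusted p = 0.56 with an estimated correlation. Interferon-stimulated genes were negative in 27 of 28 cases (median -0.53), 0 adjusted over the list alone in edgeR (camera adjusted p = 0.56), and myeloid genes in 17 of 20 (median -0.27; 0.56), with Fcgr3 at -0.51 ± 0.18 and C1qc at -0.43 ± 0.17, the latter at -0.21 with GC trends removed. The interferon median was -0.32 without Veh_LPS replicate 3 and also moved by over 1.5 times without THC_LPS replicate 2, and the myeloid median was -0.45 without THC_LPS replicate 1. THC_LPS replicate 3, with its GC trend, is in this comparison. Homeostatic microglia genes had a camera adjusted p = 0.95, activated ones 0.749, cytokines 0.769 and endocannabinoid genes 0.909, each with 0 calls by edgeR and 0 adjusted over the list alone. Tmem119 had a log2 fold change of -0.46 ± 0.17, P2ry12 0.50 ± 0.23, Igf1 0.83 ± 0.25, Lcn2 -0.85 ± 0.43, Il1b -0.41 ± 0.73, Cnr1 0.27 ± 0.18 and Cnr2 -0.50 ± 0.92. Tmem119, P2ry12 and Igf1 stood at -0.20, 0.17 and 0.47 with GC trends removed, and at -0.27, 0.17 and 0.39 without THC_LPS replicate 3. Lists of other cell types held 0 genes called by edgeR and 0 adjusted over each list alone. With the preset correlation 9 lists passed, 1 higher and 8 lower. With the estimated one 0 passed, and 2, both lower, without Veh_LPS replicate 1. The log2 fold changes of THC with and without LPS had a Pearson correlation of 0.00102 and a Spearman correlation of -0.0249 across genes, which are not independent replicates, and shared 0 edgeR calls and 3 genes at an unadjusted p under 0.01.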

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

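GC trend removal and leaving out Veh_LPS 2 and THC_LPS 3 together were chosen after seeing the data, and the other alternatives before. For LPS after vehicle the 107 edgeR calls became 202 with DESeq2, 1895 with voom weights and 166 with GC trends removed. For LPS after THC the 19 became 149 with no low-count filter, 12 with the strict filter (fewer genes tested), 453 with DESeq2, of which 13 were among the 19 (Siglec1, Plac8 and Cybb had no DESeq2 adjusted p), 975 with voom weights, 2 with only the compared groups and 146 with GC trends removed. For THC without LPS the count of 0 became 2 with no filter, 14 with DESeq2, 97 with voom weights, 9 with only the compared groups and 4 with both libraries left out. For THC with LPS it became 2 with DESeq2 and 2 with voom weights, and for the interaction 1 with DESeq2 and 0 with voom weights. EdgeR had 623, 1771 and 1167 genes at an unadjusted p under 0.05 in these 3 comparisons. Lists passing went from 12, 0, 0, 0 and 0 to 27, 15, 15, 9 and 13 with a preset correlation, in the order LPS after vehicle, LPS after THC, THC without LPS, THC with LPS and interaction, and to 7 for LPS after vehicle with both libraries left out. In the same order, 21, 10, 9, 1 and 2 of the preset passes were higher and 6, 5, 6, 8 and 11 lower. Calls shared by the LPS responses went from 15 to 132 at an unadjusted p under 0.01 and 55 with GC trends removed, and those shared by the THC comparisons from 0 to 3 at that p. Where no reason is given, the cause was not tested.

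Leaving out each library in turn gave edgeR calls from 33 (without Veh_Ctrl replicate 1) to 197 (THC_LPS replicate 3) for LPS after vehicle, 0 (THC_Ctrl replicate 1) to 160 (THC_LPS replicate 1) for LPS after THC, 0 to 5 (Veh_LPS replicate 3) for THC without LPS, 0 to 0 for THC with LPS and 0 to 1 (Veh_LPS replicate 1) for the interaction. Lists passing ranged over 7 to 14, 0 to 1, 0 to 5, 0 to 2 and 0 to 2. With the tested genes held fixed, LPS after vehicle gave 64 calls without Veh_Ctrl replicate 3 and 185 without THC_LPS replicate 3, against 80 and 197 with the filter recomputed. Other counts also moved. LPS after THC gave 13 without Veh_Ctrl replicate 1, against 19, and THC without LPS gave 2 without THC_LPS replicate 3, against 0. Planned settings for normalized values (pseudocount, value filter) were not run because counts were deposited.

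With the replicate number as a replicate block, THC without LPS had 7 edgeR calls, among them Cyr61, Egr1, Fosb and Dusp1, and 2 lists passed, immediate early genes among them, and P2ry12 in LPS after THC turned to -0.00442. LPS after vehicle had 86 calls, 83 of them among the 107, and LPS after THC 19, of which 15 were the same genes; C3, Cxcl10 and Sele missed the threshold in the former, and Ly86 and Cybb in the latter. The numbers did not pair the libraries: same-number correlations ran from -0.464 to 0.339, 6 of 18 were over 0.1, and 1 library correlated best with its own number.

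Over genes and settings, 3567 results kept direction and side of the threshold, 177 lost the call, 113 gained it and 49 changed sign; for lists these were 731, 14, 25 and 29. DESeq2 gave no adjusted p to 12 named genes in LPS after THC and 4 in THC without LPS, which are left out of these counts. In THC with LPS, 13 of 31 named genes kept their sign but moved by over 1.5 times with GC trends removed and 14 without THC_LPS replicate 3, and in the interaction 14 and 12 of 31. With voom weights 12 and 13 of 31 did so in these comparisons, and in THC without LPS 12 of 32 without THC_Ctrl replicate 2, 7 without THC_Ctrl replicate 3 and 8 each without Veh_Ctrl replicate 1 and replicate 3. No sign change had an adjusted p under 0.05 before or after, and the cause was not tested. In LPS after THC, Cnr1 turned to -0.0172 with voom weights and -0.00372 with both libraries left out, Tmem119 to 0.0499 (voom weights), 0.21 (GC) and 0.145 (both out), and P2ry12 to -0.339, -0.295 and -0.3 under the same settings. In THC without LPS, P2ry12 turned to 0.000214 with median-ratio size factors, 0.0238 with voom weights, 0.00729 with only the compared groups and 0.0163 with GC trends removed. Cnr2 in THC with LPS turned to 0.15 with both out, and Aif1 in the interaction to 0.0313 with GC trends removed. Lists that turned had unadjusted camera p of 0.974 (endocannabinoid, LPS after THC), 0.962 (myeloid, THC without LPS) and 0.73 (endocannabinoid, THC with LPS) with both out, and 0.607 (immediate early, THC with LPS) with GC trends removed.

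Leaving out single libraries gave, for results whose sign changed, log2 fold changes in LPS after THC of -0.00381 to 0.383 for Cnr1, -0.204 to 0.145 for Tmem119, -0.504 to 1.98 for Cnr2 and -0.3 to 0.177 for P2ry12. In THC without LPS they were -1.35 to 0.0713 for Lcn2, -0.33 to 0.195 for Aif1, -1.34 to 0.277 for Il1b, -0.147 to 0.0379 for Tmem119 and -0.153 to 0.0654 for P2ry12. In THC with LPS they were -0.467 to 0.115 for Aif1 and -1.35 to 0.034 for Cnr2, and in the interaction -0.916 to 0.504 for Lcn2, -0.683 to 0.933 for Il1b and -0.374 to 0.241 for Aif1. Unadjusted camera p ran from 0.173 to 0.777 for immediate early genes in LPS after vehicle, and in LPS after THC from 0.186 to 0.847 for antigen presentation and 0.468 to 0.995 for endocannabinoid genes. In THC without LPS it ran from 0.0297 to 0.834 for homeostatic, 0.396 to 0.995 for myeloid, 0.369 to 0.759 for activated microglia and 0.561 to 0.989 for cytokine genes. In THC with LPS it ran from 0.63 to 0.997 for homeostatic, 0.312 to 0.962 for immediate early and 0.458 to 0.985 for endocannabinoid genes, and in the interaction from 0.171 to 0.981 for homeostatic genes.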

Other observations

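The tests of GC trends, of THC_LPS replicate 3 alone, of the interferon interaction, of cortical markers and of LPS induction (both tests) were chosen after the result was seen. Glucocorticoid-responsive genes, which corticosterone raises in brain, held 2 edgeR calls of 18 for LPS after vehicle, both higher, and 3 adjusted over the list alone (median 0.33, or 0.17 without Veh_LPS replicate 2; camera adjusted p = 0.0734). Their mean log2 level relative to Veh_Ctrl was 0.08, 0.76 and 0.53 in Veh_LPS replicates 1, 2 and 3. Adjusted over the list alone, 1 was higher and 2 lower for LPS after THC (median -0.13; camera adjusted p = 0.734), 1 was higher for THC without LPS (median 0.14; 0.551), 5 were lower for THC with LPS (median -0.33, or -0.22 without THC_LPS replicate 2; 0.56) and 3 in the interaction (median -0.57; 0.408). Ribosomal protein genes were positive in 20 of 20 cases for LPS after vehicle (median 0.09; camera adjusted p = 0.617), a value that came from Veh_LPS replicate 1, without which the median was -0.08. They were negative in 18 of 20 for LPS after THC (median -0.20, or -0.11 without THC_Ctrl replicate 2; 0.474), with an interaction camera adjusted p = 0.415. Erythrocyte genes were negative in 8 of 8 cases after LPS in both pretreatments, with medians of -0.57 (-1.46 to -0.26 with single libraries left out) and -0.84 (-1.02 to -0.55) and camera adjusted p = 0.145 and 0.324. Mitochondrially encoded genes were positive in 12 of 12 cases for LPS after vehicle, with a median of 0.24 that was 0.02 without Veh_LPS replicate 1 and 0.37 without Veh_LPS replicate 3 (camera adjusted p = 0.362), and for THC without LPS (median 0.23; 0.551).

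Fewer genes were called for LPS after THC (19) than after vehicle (107). Lower read depth of THC_LPS is excluded as the whole cause, since the ratio of the counts had a median of 0.155 over 5 thinned draws, against 0.178 unthinned. GC trends may account for part of the gap, because the ratio was 0.88 with every library's trend removed. Leaving out THC_LPS replicate 3 with Veh_LPS replicate 2 did not close the gap (ratio 0.225). That cannot decide whether THC_LPS replicate 3 alone is the cause, because the counts also moved when other single libraries were left out. After THC they were 0, 2 and 1 without THC_Ctrl replicates 1, 2 and 3. After vehicle they were 146, 49 and 43 without Veh_LPS replicates 1, 2 and 3. A smaller interferon response after THC cannot be told apart from no difference, with an interaction camera adjusted p = 0.415 for a list that was negative in 23 of 28 cases and 3 libraries per group. DESeq2 called more genes after THC (453) than after vehicle (202), and without THC_LPS replicate 1 edgeR called 160 and 114, so the order of the counts depended on the tool and on a single library.

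Immediate early genes had higher values in THC_Ctrl than in Veh_Ctrl, with a median log2 fold change of 1.08. GC trends are argued against by a median of 1.07 with the trends removed, and a single library by medians of 0.99 (without THC_Ctrl replicate 2) to 1.28 (without THC_Ctrl replicate 1). More cortical tissue in THC_Ctrl is argued against by a median of -0.204 for cortical and hippocampal markers. A different mix of brain regions stays open for the cerebellum, whose markers were positive in 13 of 14 cases (median 0.28), but choroid plexus and Hox values did not follow the immediate early score across groups: Veh_LPS had a choroid plexus score of 0.38 and 17 to 21.5 CPM of Hox genes beside an immediate early score of 0.17, against 0.37, 1.54 to 15.2 CPM and 1.1 in THC_Ctrl, though LPS may itself act on these genes. Time of day and handling at tissue collection stay open, since in THC_Ctrl clock genes scored 0.04 ± 0.06, heat shock genes 0.09 ± 0.05, glucocorticoid-responsive genes 0.18 ± 0.12 and mitochondrially encoded genes 0.26 ± 0.05 (SD, n = 3), which decide neither, and a lasting effect of THC on neuronal activity was not tested.

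Hox genes were higher in Veh_LPS than in Veh_Ctrl. Induction that lifts every LPS library above every library without LPS is argued against. Only 3 of the 6 LPS libraries, all Veh_LPS, lay there in summed Hox CPM. THC_LPS stood at 14.2, 6.11 and, in the library with the GC trend, 0.342, against 9.39, 15.2 and 1.54 in THC_Ctrl. A weaker induction in both pretreatments cannot be told apart from tissue by this test. The marker scores described below were 2.76, 2.05 and 1.21 in THC_LPS replicates 1, 2 and 3, and 2.49, 2.85 and 1.76 in THC_Ctrl. Induction in vehicle mice alone cannot be told apart from tissue, because 3 of 3 Veh_LPS libraries lay above every Veh_Ctrl library and the marker scores below separated these groups too. A difference in how much hindbrain or spinal cord entered each library is a candidate explanation: within groups, over 12 libraries, the Hox score and a score of 9 hindbrain and spinal cord markers had a Pearson r of 0.966 (exact permutation p = 0.00463) and a Spearman rho of 0.958 (exact permutation p = 0.0116). With THC_LPS replicate 3 and THC_Ctrl replicate 3 left out, r was 0.954. The group means subtracted for that value still held both libraries. Of the markers, Slc6a5 ran from 10.8 to 63.9 CPM and Tlx3 from 0.293 to 4.77, but Glra2 and Slc5a7 were highest in THC_LPS replicate 3 (18.2 and 13.2 CPM), and the Hox genes, 8 of 12 tested, were listed after some of their values had been seen.

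The 6 libraries of each 2-group comparison make 10 splits, too few for a share under 0.05. LPS after vehicle had 107 calls in the real split, reached by 1 of 10, and at most 6 in the others, and LPS after THC had 19, reached by 1 of 10, and at most 0. THC without LPS and THC with LPS each had 0 calls in the real split, as in the other splits (10 of 10), by edgeR, which had 623 and 1771 genes at an unadjusted p under 0.05, while DESeq2 called 14 and 2 and voom with sample weights 97 and 2. For the interaction, with 1167 genes at an unadjusted p under 0.05 and 1 called by DESeq2, edgeR's real count was 0, which each of the 21 splits, the real split included, reaches by construction, so the count says nothing about chance. The highest other split called 473 genes, 3 of them among the 107 called for LPS after vehicle and 0 among the 19 called by edgeR for LPS after THC. Such a count points to a structure of the samples. The split set Veh_Ctrl replicates 1 and 2, THC_Ctrl replicates 2 and 3, Veh_LPS replicate 1 and THC_LPS replicate 3 against the other libraries. Spearman correlations with gene length were -0.506 to -0.0378 in the former, except 0.245 in THC_LPS replicate 3, and 0.0425 to 0.481 in the latter. Veh_Ctrl replicates 1 and 2 and THC_LPS replicate 3 also had the lowest Hox scores (-3.68 to -3.37). Whether either gave the 473 calls was not tested.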
